A study of Mus musculus with 6 samples.

How the data were processed

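Total RNA of 6 samples of sorted mouse small-intestinal epithelial lymphocytes was sequenced by the submitters after library preparation with a directional kit (NEBNext Ultra II Directional), per the labels' protocols. The sample titles place 3 libraries in the B220−CD3ε+CD45+ group (T cells) and 3 in the B220+CD3ε+CD45+ group (X cells), with replicates numbered 1 to 3 in each. The deposited values are whole-number read counts per gene, not normalized, for 55487 genes, of which 29211 had no count in any library. Per the submitters' processing notes, the authors used FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 1.6.3 with the mm10 genome build. The options of trimming, alignment and counting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Of the gene models, 98.73% had the same coordinates as in GENCODE release M21, and coordinates are given as deposited, 1-based. Gene symbols are those of the deposited table, and exonic lengths were taken from that release.

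Whether the deposited counts used strand was checked on models of miRNA precursors that lie wholly inside an intron of a protein-coding gene with at least 1000 counts. Such models pick up unspliced reads of their host. Of 312 on the host's strand 154 (49.4%) had a count, and of 85 on the opposite strand 45 (52.9%). Simulated counts gave 52.9% on the opposite strand with strand ignored and 3.53% with strand used. Reads of overlapping genes on opposite strands were therefore treated as not distinguishable, although the kit marks strand. Among named genes, an opposite-strand gene with over 10% of the named gene's counts overlaps Cd3e, Cox6a2, Csf2, Dusp1, Il21, Itga4, Slamf7, St3gal6, St6gal1, Thra, Tpi1 and Trdc, and the values of these genes carry that uncertainty. Members of near-identical families (Trbc1 and Trbc2, the Trgc and Trgv segments, Klra6, Klra7 and other Ly49 genes, Lyz1 and Lyz2, Defa24, Hbb-bs) can share reads and are uncertain to that extent.

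Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: trimmed-mean scaling, the default filter on low counts (filterByExpr, minimum count 10, minimum total 15), a robust quasi-likelihood fit and the quasi-likelihood F test on a design with the group alone. Fold changes are B220+ minus B220− on the log2 scale, and adjusted p-values are Benjamini-Hochberg over the 14722 genes tested, called under 0.05. Normalised counts (CPM) use the scaled library sizes. The scaling factors lay between 0.990 and 1.01. On 5 simulated data sets, each with 200 of at least 14476 genes changed, the test recovered 49.2% of genes changed 1.5-fold, 76.0% of those changed 2-fold, 89.5% of those changed 3-fold and 95.2% of those changed 4-fold. Of 856 calls 89 (10.4%) were false, and 14.3% were with the replicate block, both above the nominal rate. The simulated libraries held no effect shared by a pair, so the rate with the block need not hold for paired libraries. Pairs of libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom 7.26 to 16.3), so no library was counted as a repeat of another.

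The replicate numbers of the titles were checked for pairing by correlating, across genes, each library's deviations from its group mean. Libraries with the same number correlated at 0.345, 0.323 and 0.291, and those with different numbers at −0.24 to −0.060. Deviations sum to 0 within a group, so the negative values follow in part from the positive ones. On these correlations the numbers were taken to pair the libraries, a relation found from the data and not stated in the labels. With 3 libraries per group, the numbered matching could also be the best one by chance. The columns of the deposited table carry other numbers (1, 3 and 7 for T cell replicates 1 to 3, and 4, 6 and 8 for X cell replicates 1 to 3), which do not mark these pairs, so every value with the replicate block rests on this inference. The replicate block was an alternative, and its value is given beside a result where it changes a call or moves a count by over 1.5 times.

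In total 30 gene lists with 611 entries were fixed before the data were examined, covering receptor components, natural intraepithelial lymphocytes, cytokines, cytotoxicity, naive, helper and resident T cells, activation, costimulation, inhibitory receptors, RXR, CD45 processing, cell cycle, apoptosis, interferon response, MHC class II, metabolism, mitochondrial mRNA and 10 sets of markers of other cell types. Entries were matched by symbol (603) or by gene identifier (4), and 4 were not matched. The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation of 0.01), which compares a list with all other genes. Of these, 8 were called (7 lower and 1 higher) and 0 with an estimated correlation. The estimated setting also takes its degrees of freedom from the few libraries, which lowers its power, so a lost call need not mean a high correlation. In a simulation of 50 lists of 20 genes, all 10 lists shifted 1.5-fold were found and 0 others. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely. The self-contained fry test called 11 lists in 1 direction, the same as camera except for the plasma cell list (adjusted p = 0.0608), which it did not call, and 4 more that fell: receptor components (0.0121), tissue residence (0.0184), CD45 processing (0.0109) and natural killer and innate lymphoid genes (0.00127).

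Genes were named by a rule fixed before the data were examined. It took 18 fixed genes of the gates, lineages, RXR and Ptprc splicing, and the 10 largest increases and 10 largest decreases among called genes with average log2 CPM of at least 3 and no overlap between the groups, leaving out receptor segments and models without a proper symbol. From each list it took up to 4 called members with the largest change and average log2 CPM of at least 1, or up to 2 of the most expressed where none was called. Receptor segments were summarised, naming at most 3 each. Other genes (among them Trgc2, Trgv7, Thy1, Lat, Ifng, Cd7, Foxp3, Fgl2, Tnfrsf9, Tigit, Gzma, Gzmb, Itgad and members completing a count of 5 or fewer) were named after their values were seen. Some genes that the rule would name are not reported here. Where a group had 1 to 3 counts of a gene, the ratio of depth-corrected counts is given with an exact 95% counting interval.

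The alternative settings chosen before the data were examined were RLE, upper-quartile and total-count scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, a test against a 1.5-fold change (glmTreat), removal of receptor segments and mitochondrial genes, the replicate block and leaving out each library. Thinning to the smallest library, the block together with glmTreat, and a camera test of 1400 Gene Ontology processes with 10 to 300 tested members were added after seeing the data. Thinning had been set beforehand only as a test of library depth.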

Results

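RNA sequencing was performed on sorted lymphocytes from the epithelial layer of the small intestine of wild-type C57BL/6J mice. All sorted cells carried CD3ε, a subunit of the T cell receptor complex, and CD45, the pan-leukocyte phosphatase encoded by Ptprc. They were separated by B220, a form of CD45 best known from B cells, into B220-negative cells, labelled T cells, and B220-positive cells, labelled X cells. Each group had 3 libraries. Each library pools many cells, so a gene can differ between the groups through the mix of cells as well as within cells. The deposited gene counts summed to 18773165, 17753655 and 11320363 in B220− replicates 1, 2 and 3, and to 11810859, 39591312 and 14173322 in B220+ replicates 1, 2 and 3. Intervals given for low counts cover counting error only. No label states that the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, part of which could be technical. Mitochondrial mRNA took 0.926% to 1.13% of counts, and the most abundant gene, Gzma, took 0.803% to 1.42%.

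The design has 1 comparison, B220+ against B220− CD3ε+ cells, which asks how the B220+ population, described in the series title as producing GM-CSF and carrying CD8αα, differs from the remaining T cells of the same epithelium. Cd4, the helper coreceptor, fell from 177 ± 46.8 in B220− to 7.63 ± 0.839 CPM in B220+ cells (counts normalised to library size, mean ± SD, n = 3 per group), and Cd8b1, the CD8β chain, fell from 215 ± 64.5 to 24.5 ± 4.89 CPM. Cd8a, the chain that forms CD8αα homodimers, rose 1.29-fold. Csf2, which encodes GM-CSF, rose 5.14-fold, while Il17a and Il22 fell. The lists of naive T cell genes (11 of 13 tested members called lower) and of interferon-stimulated genes (15 of 27) were lower as sets by the camera test, and each had an adjusted p of 0.146 with an estimated correlation. Of 14722 genes tested with edgeR's quasi-likelihood test, 1639 had a Benjamini-Hochberg adjusted p under 0.05, of which 821 were higher and 818 lower in B220+ cells. The decreases were larger: 341 genes were at least 2-fold lower and 218 at least 2-fold higher, and 87 were at least 8-fold lower against 6 at least 8-fold higher. With the replicate number as a block the count was 2569 (1303 higher and 1266 lower), and 1621 of the 1639 genes were among them. Without B220+ replicate 2 it was 970, without B220− replicate 3 it was 1029, and against a fold change of 1.5 it was 337.

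**Figure D1:**
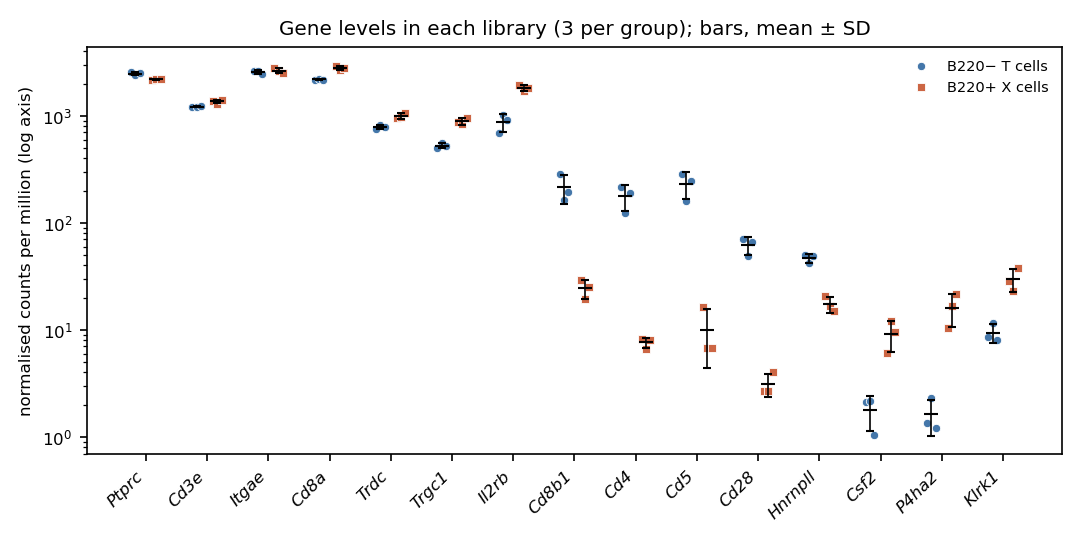
Normalised counts (CPM, log axis) of 15 genes in each of the 3 B220− T cell libraries (circles) and 3 B220+ X cell libraries (squares), with bars for mean ± SD. Ptprc and Itgae differ by 1.13-fold and 1.03-fold between the groups, Cd8b1, Cd4, Cd5, Cd28 and Hnrnpll are lower in every B220+ library, and Csf2, P4ha2, Klrk1 and Il2rb are higher in every B220+ library.

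Ptprc (ENSMUSG00000026395, mm10 chromosome 1, 138062861 to 138175708) stood at 2481 ± 90.3 CPM in B220− and 2188 ± 28 CPM in B220+ cells, a log2 fold change of −0.18 (SE 0.075) that did not pass the edgeR test (adjusted p = 0.163, but 0.041 with DESeq2). Gene counts do not separate the CD45 isoforms. Cd3e (0.17, edgeR adjusted p = 0.184) and Itgae, the αE integrin of intraepithelial lymphocytes (0.037, edgeR adjusted p = 0.854), did not pass either. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) stood at 2184 ± 40.2 and 2810.3 ± 132 CPM, log2 fold change 0.36 (SE 0.077), with an edgeR adjusted p of 0.00779, which became 0.0537 without B220− replicate 3. Its neighbour Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494) fell by 3.16 on the log2 scale (SE 0.30, edgeR adjusted p = 0.00447). Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) fell by 4.56 (SE 0.27, edgeR adjusted p = 3.79e-04). In all 3 B220+ libraries Cd8b1 and Cd4 were below every B220− library.

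The constant segments of the αβ receptor did not pass the test, with log2 fold changes of 0.0050 for Trac, 0.11 for Trbc1 and −0.038 for Trbc2 and edgeR adjusted p of 0.980, 0.493 and 0.845. Of the 5 constant segments of the γδ receptor, 3 were called higher in B220+ cells. Trgc1 (ENSMUSG00000076749, chromosome 13, 19214103 to 19217024) rose from 526 ± 27 to 890.2 ± 64.8 CPM (log2 fold change 0.76, SE 0.077, edgeR adjusted p = 4.46e-05). Trdc (ENSMUSG00000104876, chromosome 14, 54142851 to 54148868) rose from 783 ± 34.6 to 995 ± 66.7 CPM (edgeR adjusted p = 0.00977, or 0.0524 without B220− replicate 3), and Trgc4 was 1.20-fold higher (edgeR adjusted p = 0.0473) but passed in none of the 6 fits that left out 1 library (adjusted p 0.0502 to 0.193). Trgc2 was not called (551 ± 30.9 and 639 ± 30.1 CPM, edgeR adjusted p = 0.0808, but 0.0155 with the replicate block). Among V segments, 5 of 78 tested were higher and 3 lower, and the most expressed of those higher was Trgv7, at 136 ± 18.4 and 246 ± 14.4 CPM (edgeR adjusted p = 1.04e-04). In the list of T cell receptor components and coreceptors, 4 of 23 tested members were called higher and 9 lower (6 and 9 adjusted over the list alone, 7 and 9 with the replicate block). Those lower included Cd5 (24.7-fold), an inhibitor of receptor signalling, Cd28 (20.2-fold), the main costimulatory receptor, Cd6 (11.9-fold), Thy1 (4.55-fold) and the adaptor Lat (2.75-fold). The edgeR adjusted p of Cd5 was 0.00938, and 0.0505 without B220+ replicate 2. The camera test of this list gave an adjusted p of 0.149 in the lower direction (0.0434 with no filter on low counts), on a median log2 fold change of 0.0050 and a mean of −1.02.

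Cytokine genes fell as a group, with Csf2 going the other way. Csf2 (ENSMUSG00000018916, mm10 chromosome 11, 54247271 to 54249667, minus strand) rose from 1.77 ± 0.623 to 9.25 ± 2.97 CPM, a log2 fold change of 2.36 (SE 0.30, edgeR adjusted p = 4.90e-04), and was higher in all 3 B220+ libraries than in any B220− library. It rested on 89 counts over the B220− and 685 over the B220+ libraries, and the overlapping antisense gene Gm12223, whose reads cannot be told apart from those of Csf2, rose 5.66-fold. Il17a had 1057 counts over the 3 B220− and 3 over the 3 B220+ libraries, a depth-corrected ratio of 485 (95% counting interval 166 to 2357), and Il22, which acts on epithelium, had 394 and 2, a ratio of 271 (74.6 to 2249). Il21 fell 71.3-fold, Tnfsf11 (RANKL) 13.5-fold and Ifng 2.50-fold. In the list of lymphocyte cytokines and chemokines, 2 of 20 tested members were called higher and 12 lower (3 and 13 adjusted over the list alone, 4 and 13 with the replicate block), and the list was lower as a set (camera adjusted p = 4.02e-06). With an estimated correlation its adjusted p was 0.146. Besides Csf2, Fgl2, a secreted fibrinogen-like protein of regulatory and intraepithelial lymphocytes, was higher (1.36-fold).

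Genes of natural intraepithelial lymphocytes, the innate-like CD8αα cells of the gut epithelium, rose as a set (camera adjusted p = 1.02e-05, adjusted p = 0.146 with an estimated correlation). In this list, 10 of 26 tested members were called higher and 2 lower (16 and 2 adjusted over the list alone). Il2rb, the receptor chain shared by interleukin-2 and interleukin-15, rose from 871 ± 162 to 1819 ± 127 CPM (edgeR adjusted p = 4.71e-04). Klrk1, the NKG2D receptor, rose 3.12-fold (edgeR adjusted p = 0.00105), and Cd7 rose 1.88-fold from 1847 ± 267 CPM. Klra7, of the Ly49 family, was 3.02-fold higher (edgeR adjusted p = 0.0116), but its adjusted p exceeded 0.05 without each B220− library in turn and reached 0.112 without B220− replicate 1. The 2 members that fell were Btla, an inhibitory receptor (6.61-fold), and Itgb7, the partner chain of Itgae (from 1024 to 744 CPM).

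The cytotoxic granule list did not differ as a set (camera adjusted p = 0.421). In it, 3 of 19 tested members were called higher and 2 lower (6 and 2 adjusted over the list alone, 6 and 4 with the replicate block), namely Klrk1, Klrd1 (1.72-fold) and Crtam (1.20-fold) higher and Klrg1 (2.58-fold) and Slamf7 (1.51-fold) lower. Gzma stood at 8789.6 ± 952 and 11804 ± 2282 CPM and Gzmb at 5456 ± 1152 and 5650.5 ± 1433 CPM (edgeR adjusted p = 0.0737 and 0.935, but 0.00135 for Gzma with the replicate block). Among inhibitory receptors and genes of chronic stimulation, 6 of 14 tested members were called higher and 4 lower (8 and 5 adjusted over the list alone) (camera adjusted p = 0.364, median log2 fold change 0.46, mean −0.013). Lag3 rose 2.05-fold and Tigit 1.66-fold, whereas Pdcd1 (PD-1) fell 2.24-fold and Havcr2 (TIM-3) 2.39-fold. Ctla4 was 2.40-fold lower, with an edgeR adjusted p of 0.0333 that exceeded 0.05 in 4 of the 6 fits that left out 1 library (up to 0.114 without B220+ replicate 2).

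Genes of naive and recirculating T cells had the lowest median log2 fold change of the 28 lists tested as sets, at −1.75. Of these, 0 of 13 tested members were called higher and 11 lower (0 and 11 adjusted over the list alone) (camera adjusted p = 5.37e-12). With an estimated correlation the adjusted p was 0.146. Ccr7, the chemokine receptor for lymph node entry, fell from 21.7 ± 4.31 to 0.682 ± 0.306 CPM, S1pr1, the receptor for tissue exit, fell 15.6-fold, and Igfbp4 fell 145-fold. Il7r, the interleukin-7 receptor, fell 6.95-fold from 128 ± 26.5 CPM. Transcription factors and receptors of helper, innate-like and regulatory T cells were lower as well. In that list, 0 of 21 tested members were called higher and 12 lower (2 and 15 adjusted over the list alone, 3 and 13 with the replicate block) (camera adjusted p = 1.41e-08). Its adjusted p was 0.146 with an estimated correlation. Il18r1 fell 30.9-fold, Maf 10.8-fold and Foxp3, of regulatory T cells, 2.03-fold. Among costimulatory receptors and activation markers, 2 of 15 tested members were called higher and 8 lower (4 and 9 adjusted over the list alone) (camera adjusted p = 0.00922). The adjusted p was 0.146 with an estimated correlation. Cd40lg (CD40 ligand) fell 14.7-fold and Icos 10.2-fold, while the transcription factor gene Batf3 rose 5.44-fold. Tnfrsf9 (4-1BB) was 2.35-fold higher, with an edgeR adjusted p of 0.0113 that became 0.135 with the replicate block. In the tissue residence and gut homing list, 2 of 20 tested members were called higher and 8 lower (4 and 8 adjusted over the list alone, 5 and 9 with the replicate block) (camera adjusted p = 0.112). The integrin chain Itga4 fell 1.87-fold, the chemokine receptors Cxcr3 and Ccr9 fell 1.78-fold and 1.44-fold, and Zfp683 (Hobit) fell 5.67-fold.

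**Figure D2:**
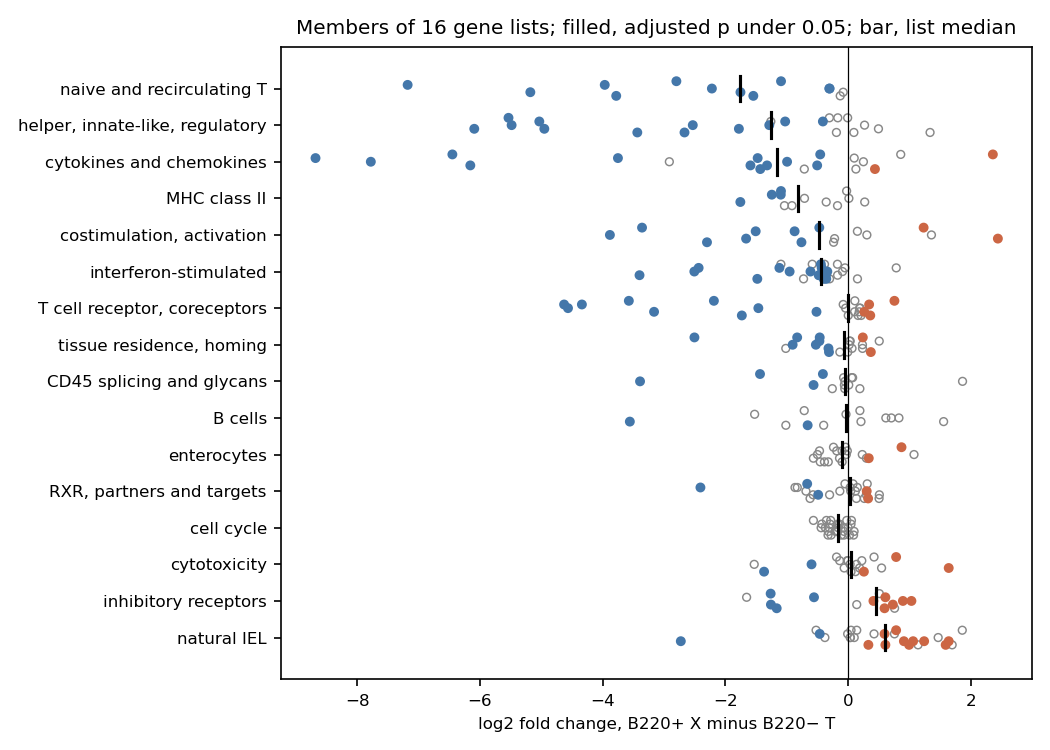
Log2 fold change, B220+ X minus B220− T cells, of every tested member of 16 of the 30 gene lists (filled points, adjusted p under 0.05 over all genes; open points, not called; bar, list median). The medians run from −1.75 in the naive and recirculating list to 0.60 in the natural intraepithelial list.

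Interferon-stimulated genes were lower in B220+ cells as a set (camera adjusted p = 1.04e-08, adjusted p = 0.146 with an estimated correlation). In this list, 0 of 27 tested members were called higher and 15 lower (1 and 16 adjusted over the list alone, 1 and 17 with the replicate block). Oas3, an antiviral 2′-5′ oligoadenylate synthetase, fell from 36.2 ± 13.1 to 6.43 ± 0.235 CPM, Mx1 fell 5.40-fold and Ifit1bl1 2.17-fold. Genes of MHC class II presentation were lower too (camera adjusted p = 0.00100, adjusted p = 0.146 with an estimated correlation). There, 0 of 12 tested members were called higher and 4 lower (0 and 5 adjusted over the list alone), and the 4 were H2-Aa (2.36-fold), H2-Eb1 (2.14-fold), H2-Ab1 (2.13-fold) and H2-Ob (3.37-fold). Levels of H2-Aa were 13.1 ± 1.27 and 5.54 ± 1.27 CPM. Genes of other antigen-presenting cells moved both ways. Lyz2 fell 6.06-fold and the B cell gene Blk 11.8-fold, Batf3 rose, and the macrophage and dendritic cell list had a median log2 fold change of 0.45. Whether the class II transcripts came from the T cells was not tested.

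The series title names an agonist of the retinoid X receptor (RXR), and none of the 6 libraries is labelled as treated with it. Rxra (6.64 ± 2.12 and 4.34 ± 0.829 CPM, edgeR adjusted p = 0.180) and Rxrb (92.7 ± 4.57 and 84.6 ± 4.83 CPM, edgeR adjusted p = 0.325) did not pass the test. In the list of RXR, its partner receptors and their targets, 2 of 24 tested members were called higher and 3 lower (3 and 3 adjusted over the list alone, 6 and 4 with the replicate block) (camera adjusted p = 0.988, median 0.040, mean −0.19, test in the lower direction). Rara, a retinoic acid receptor, fell 1.59-fold (edgeR adjusted p = 5.59e-04) and Dhrs3, a retinaldehyde reductase, fell from 2.07 ± 0.292 to 0.413 ± 0.255 CPM. Thra was 1.40-fold lower and Abcg1 and Plin2 were 1.26-fold and 1.24-fold higher, and their edgeR adjusted p exceeded 0.05 in 4, 2 and 5 of the 6 fits that left out 1 library, reaching 0.127 and 0.0657 without B220+ replicate 2 and 0.154 without B220+ replicate 1.

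Hnrnpll (ENSMUSG00000024095, mm10 chromosome 17, 80029487 to 80062334), a splicing factor that promotes skipping of the variable exons of Ptprc, fell from 46.9 ± 4.33 to 17.5 ± 2.99 CPM (log2 fold change −1.43, SE 0.12, edgeR adjusted p = 1.26e-05). It was lower in all 3 B220+ libraries than in any B220− library. Whether Hnrnpll was lower within cells, or cells that express it were fewer, was not tested. In the list of CD45 splicing regulators and glycosylation enzymes, 0 of 14 tested members were called higher and 4 lower (1 and 4 adjusted over the list alone, 1 and 4 with the replicate block) (camera adjusted p = 0.163). The other 3 were the sialyltransferases St6gal1 (10.5-fold), St3gal6 (1.48-fold) and St3gal1 (1.33-fold).

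No member of the cell cycle list was called among 28 tested, with or without the replicate block (camera adjusted p = 0.638), with Hmgb2 at 289.8 ± 36.6 and 309 ± 18.4 CPM and Pcna at 198 ± 16.7 and 189 ± 15.5 CPM. Without B220− replicate 1 the camera direction of this list turned to higher, with an adjusted p of 0.00845. Of 39 nuclear genes of oxidative phosphorylation 0 were called by edgeR, or 2 lower with the replicate block (camera adjusted p = 0.532), and of 11 mitochondrial mRNAs 0 (camera adjusted p = 0.336, or 0.0251 in the lower direction without B220+ replicate 3). In the glycolysis list, 1 of 20 tested members was called higher and 1 lower (2 and 1 adjusted over the list alone, 2 and 5 with the replicate block), Tpi1 (1.37-fold) and Pfkl (1.22-fold) respectively (camera adjusted p = 0.533). Among genes of cholesterol synthesis and uptake, 1 of 23 tested members was called higher and 0 lower (0 and 0 adjusted over the list alone), which was Dhcr7 (1.17-fold, camera adjusted p of the list 0.398). Pfkl and Dhcr7 each lost the call in 5 of the 6 fits that left out 1 library, with edgeR adjusted p up to 0.153 and 0.163, both without B220− replicate 3. Among death receptors and BCL2 family genes, 3 of 25 tested members were called higher and 4 lower (5 and 4 adjusted over the list alone, 7 and 4 with the replicate block) (camera adjusted p = 0.994). The pro-apoptotic Bcl2l11 (BIM) rose 1.69-fold to 201 ± 5.71 CPM, and Bik fell 3.30-fold. Among early activation genes, which tissue dissociation also raises, 1 of 21 tested members was called higher and 2 lower (1 and 2 adjusted over the list alone, 3 and 11 with the replicate block) (camera adjusted p = 0.0804, but 0.00275 in the lower direction with the replicate block, 0.0434 with no filter on low counts, 0.00972 without B220− replicate 1 and 0.00104 without B220+ replicate 2). With an estimated correlation its adjusted p was 0.805, or 0.582 with the block. The 3 called were Egr3 (1.39-fold higher), Zfp36 (1.32-fold lower) and Dusp1 (1.21-fold lower), which lost the call in 5, 5 and 3 of the 6 fits that left out 1 library, with edgeR adjusted p up to 0.192, 0.121 and 0.0873.

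Markers of other cells that the gates could hold were measured in the same libraries. The B cell markers Ms4a1 and Cd79a were below the filter on low counts, with 2 and 26 counts over the B220− and 1 and 45 over the B220+ libraries. In the B cell list, 0 of 13 tested members were called higher and 2 lower (2 and 3 adjusted over the list alone, 2 and 2 with the replicate block) (camera adjusted p = 0.787), Blk and Ralgps2 (1.58-fold). The 2 higher with the replicate block were the heavy chain genes Ighm and Ighd. Their edgeR adjusted p were 8.41e-07 and 4.52e-04 with the block, and 0.0950 and 0.0775 without it. Of immunoglobulin segments, 0 of 51 tested were higher and 4 lower, among them Ighv1-72 and Igkv9-124, both at under 1.5 CPM, which lost the call in 1 and 3 of the 6 fits that left out 1 library (edgeR adjusted p up to 0.0654 and 0.130, both without B220+ replicate 2). In the plasma cell list, 0 of 12 tested members were called higher and 3 lower (0 and 3 adjusted over the list alone) (camera adjusted p = 0.0407). Its adjusted p was 0.599 with an estimated correlation, and 0.162, 0.107 and 0.115 without B220− replicate 3, B220+ replicate 1 and B220+ replicate 2. The 3 lower were Irf4 (3.16-fold), Sdc1 (4.36-fold) and Prdm1 (1.25-fold), and activated T cells also express Irf4 and Prdm1. Sdc1 and Prdm1 lost the call in 3 and 4 of the 6 fits that left out 1 library, with edgeR adjusted p up to 0.127 and 0.154. In the absorptive enterocyte list, 2 of 19 tested members were called higher and 0 lower (2 and 0 adjusted over the list alone) (camera adjusted p = 0.918, median −0.10, mean −0.036, test in the higher direction), namely Lgals3 (1.83-fold) and Dgat1 (1.27-fold, edgeR adjusted p 0.0593 without B220+ replicate 3). In the secretory and crypt epithelium list, 0 of 12 tested members were called higher and 0 lower (0 and 0 adjusted over the list alone, 0 and 2 with the replicate block) (camera adjusted p = 0.421, or 0.00445 in the lower direction without B220+ replicate 3), and its Paneth cell gene Lyz1 stood at 11.5 ± 13.3 and 11.6 ± 14.6 CPM.

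In the macrophage and dendritic cell list, 1 of 10 tested members was called higher and 1 lower (3 and 2 adjusted over the list alone, 2 and 1 with the replicate block), Batf3 and Lyz2 respectively (camera adjusted p = 0.402). In the plasmacytoid dendritic cell list, 2 of 9 tested members were called higher and 4 lower (5 and 4 adjusted over the list alone) (camera adjusted p = 0.533, but 0.00659 in the higher direction with no filter on low counts). Cox6a2 (3.81-fold) and Ptprs (1.37-fold) were higher, and Bst2, Ccr9, Runx2 and Lair1 lower, Lair1 with an edgeR adjusted p of 0.0234 that exceeded 0.05 in 4 of the 6 fits that left out 1 library (up to 0.120 without B220+ replicate 2). Cox6a2 lies inside Itgad on the opposite strand, and Itgad, with 126 ± 34.6 and 401 ± 16.9 CPM, rose 3.18-fold, so their reads cannot be told apart. Siglech, a plasmacytoid marker below the filter and named after its counts were seen, had 1, 0 and 3 counts in the B220− and 3, 40 and 53 in the B220+ libraries. The 7 members below the filter, Siglech, Spib, Ly6d and Klk1 among them, together held 9, 12 and 19 counts in the B220− and 15, 127 and 131 in the B220+ libraries. Among natural killer and innate lymphoid genes, 1 of 12 tested members was called higher and 5 lower (4 and 5 adjusted over the list alone, 2 and 6 with the replicate block) (camera adjusted p = 0.113, or 0.0471 in the lower direction without B220+ replicate 3). Klrb1c (NK1.1) rose 2.14-fold, and those lower included Eomes (2.43-fold) and Il7r. In the stroma and endothelium list, 0 of 6 tested members were called higher and 1 lower (0 and 1 adjusted over the list alone, 0 and 2 with the replicate block), Pdgfrb (camera adjusted p = 0.632), and its most expressed member, Vim, stood at 365 ± 81.9 and 309 ± 37.2 CPM (edgeR adjusted p = 0.507, but 0.0222 with the replicate block). The granulocyte and mast cell list and the erythroid and platelet list had too few tested members for a set test. In the former 2 of 3 were lower, Mcpt1 (12-fold, with edgeR adjusted p up to 0.0594, without B220+ replicate 2) and Mmp9 (69 and 2 counts, a ratio of 47.5 with a 95% counting interval of 12.7 to 400.2), and in the latter 0 of 4 were called.

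Among genes with an average log2 CPM of at least 3, the 10 with the largest increase were P4ha2, Adamtsl2, Dnm3, Tmprss6, Slc38a8, Spp1, C1qtnf6, Klra6, Map2 and Cox6a2. P4ha2 (ENSMUSG00000018906, mm10 chromosome 11, 54100095 to 54131665), a collagen prolyl hydroxylase encoded 116 kb from Csf2, rose from 1.63 ± 0.602 to 16.2 ± 5.63 CPM (log2 fold change 3.28, SE 0.33, edgeR adjusted p = 3.79e-04). Adamtsl2 rose 5.37-fold, C1qtnf6 4.21-fold, the neuronal microtubule protein Map2 3.83-fold and the membrane serine protease Tmprss6 4.85-fold. Dnm3, Spp1 (osteopontin) and Klra6 were 4.86-fold, 4.53-fold and 4.03-fold higher, and their edgeR adjusted p of 0.0230, 0.0196 and 0.00837 became 0.128, 0.0894 and 0.111 with the replicate block. Without B220− replicate 3 these were 0.0995, 0.0901 and 0.0525, and that of Slc38a8 (4.53-fold) was 0.0552. The 10 with the largest decrease were Il17a, Podnl1, Ccr7, Hlf, Il18r1, Cd5, Cd4, Cd28, S1pr1 and St8sia1. Podnl1, a leucine-rich repeat protein, fell from 32.2 ± 8.82 to 0.749 ± 0.160 CPM (edgeR adjusted p = 9.25e-07), the transcription factor gene Hlf fell 33.7-fold, and St8sia1, which makes ganglioside GD3, fell 14.9-fold.

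**Figure D3:**
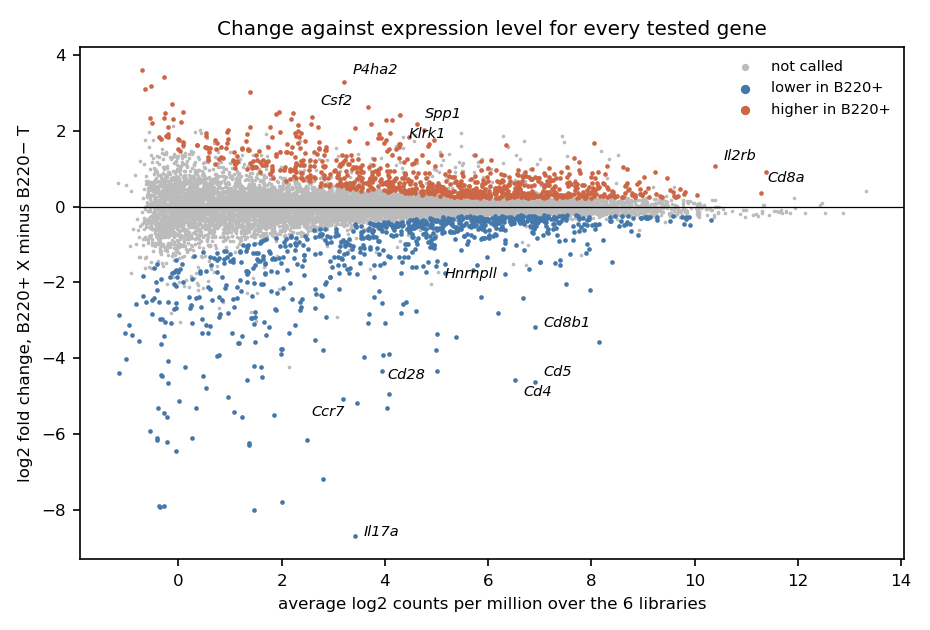
Log2 fold change (B220+ X minus B220− T cells) against average log2 CPM for the 14722 tested genes, with the 821 called higher and the 818 called lower in colour. Il17a, fitted at −8.68 on 3 counts in B220+ cells, lies lowest, and Csf2 (2.36) and P4ha2 (3.28) lie above 0.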

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

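As settings, thinning all libraries to the smallest, the block combined with glmTreat and the Gene Ontology test were chosen after the data were seen, and all others before. The use of thinning as a test of depth had been set before. The count of 1639 called genes stayed within 1.5 times, at 1520 to 2211, under 3 other scalings, 2 other filters, DESeq2, both limma-voom fits, removal of receptor segments and mitochondrial genes, and thinning. Testing against a 1.5-fold change gave 337 (85 higher, 252 lower), by construction fewer. The replicate block gave 2569 (1303 higher, 1266 lower), and the block with that fold threshold 489 (163 higher, 326 lower), and the cause of the gain was not tested beyond the pairing of the libraries. Leaving out 1 library gave 970 to 1789 genes, 425 to 966 higher and 545 to 823 lower, with fewer samples in each fit. It fell by over 1.5 times without B220+ replicate 2, the deepest library (970, with 425 higher and 545 lower), and without B220− replicate 3 (1029, with 441 higher).

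Of the 8 gene lists called, 0 kept the call with an estimated correlation (adjusted p 0.146 for 7 lists and 0.599 for plasma cells). In the costimulation list the estimated correlation was −0.013, below the preset 0.01, so a higher correlation does not account for the lost call there. In the others called it ran from 0.034 (MHC class II) to 0.43 (naive T cells). The estimated setting also has far fewer degrees of freedom, set by the libraries and not by the genes. The lost calls therefore do not by themselves show that correlation undid a result, and the share of each was not tested. RLE scaling called 8 lists, no filter 12, the replicate block 9, and leaving out 1 library 7 to 11. The cell cycle list reversed without B220− replicate 1 (adjusted p 0.00845, higher, against 0.638 in all libraries and up to 0.978 without B220+ replicate 3), and the cause was not tested. Of 113 named genes tested, 93 were called, 45 of these kept the call under every setting that tested them, 64 under every setting but the tests against a 1.5-fold change, and 0 reversed. Those tests ended 39 calls, or 35 with the replicate block. Leaving out 1 library ended 21 without B220− replicate 3, 19 without B220+ replicate 2, 15 without B220+ replicate 1, 13 without B220+ replicate 3, 9 without B220− replicate 1 and 7 without B220− replicate 2. The replicate block ended the calls of Dnm3, Spp1, Klra6 and Tnfrsf9 and added calls of Vim, Gzma, Trgc2, Kit, Ighm, Ighd and the early activation list, the latter not with an estimated correlation (adjusted p 0.582). Other scalings moved the median of all genes by at most 0.0074 on the log2 scale. In simulation, about 1 of 2 changes of 1.5-fold was found, so uncalled genes can differ by that much.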

Other observations

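All genes of this paragraph were named after their values were seen. Several genes of natural intraepithelial lymphocytes and innate-like cells had large fold changes but varied between the B220− libraries. Kit, the stem cell factor receptor, stood at 74.2 ± 26.7 and 269 ± 62 CPM, the signalling adaptors Tyrobp (DAP12) and Fcer1g at 83.1 ± 48 and 269.9 ± 8.27 CPM and at 154 ± 68.3 and 427 ± 10.9 CPM, and Gcnt1, which builds the core-2 glycans carried by B220, at 33.4 ± 17.7 and 121 ± 14.2 CPM. Their edgeR adjusted p were 0.0543, 0.147, 0.108 and 0.0998, and with the replicate block 4.12e-07, 0.222, 0.180 and 0.125. Itgad, the αD integrin, rose 3.18-fold (edgeR adjusted p = 0.00661). The immunoglobulin heavy chain genes Ighm (155 ± 36.6 and 253 ± 34.4 CPM) and Ighd (4.07 ± 2.27 and 12 ± 3.55 CPM) were higher in all 3 B220+ libraries than in any B220− library, with edgeR adjusted p of 0.0950 and 0.0775, and 8.41e-07 and 4.52e-04 with the replicate block. Among γ chain V segments, Trgv7 rose 1.80-fold, Trgv4 1.41-fold and Trgv1 1.36-fold.

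Of 1400 Gene Ontology processes, a test added after the data were seen, 17 were called by camera and all were lower in B220+ cells. They included the cellular response to interferon-beta (17 of 36 members lower, 0 higher, adjusted p = 3.79e-04), positive regulation of interleukin-17 production (8 of 14 lower, adjusted p = 0.00308), cytoplasmic translation (3 of 31 lower, adjusted p = 0.00308) and phospholipid translocation (5 of 11 lower, adjusted p = 0.0402). With an estimated correlation 0 were called (adjusted p = 0.993 for each of these). That setting has few degrees of freedom, so over 1400 processes it could hardly call any, and it does not decide on the 17. The ribosomal protein genes took 3.83% to 4.18% of counts in B220− and 3.24% to 3.79% in B220+ libraries.

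For the patterns below, the tests on the enterocyte list, on plasmacytoid markers, on Csf2, on P4ha2 and on residual Cd4, Cd5 and Cd28 were chosen only after the results were seen. The first pattern is the 1639 genes called between the groups. The share held by the 2 epithelial lists (0.122%, 2 genes) cannot exceed 1.89%, as 31 members were tested, and decides nothing. Epithelial RNA in 1 group would move epithelial genes by at least as much as the genes it explains, but the 19 tested enterocyte genes had a median log2 fold change of −0.097 (95% interval −0.38 to 0.23), and the 14 under 5 CPM in both groups −0.21 (−0.46 to −0.011), against medians of 0.61 in the genes called higher and −0.79 in those called lower. Thinning every library to the smallest kept 87.31% (1431 genes) with the same sign. The Spearman correlation of fold change with exonic length across genes was 0.0636, and 46.15% (6 of 13) of the B cell list had a positive fold change. Depth and gene length are thus argued against as the source of the pattern. Epithelial RNA and B cells in the B220 gate are argued against as the source of most of it. Within the B cell list Ighm and Ighd were higher with the replicate block, so some B cells in the gate are not excluded. The 7 plasmacytoid dendritic cell markers below the filter stood in B220+ replicate 1 at 0.137 of their level in replicate 3 (95% counting interval 0.0747 to 0.235). Genes brought by such cells would differ as much, but over the 821 genes called higher the median ratio of the excess over the B220− mean in replicate 1 to that in replicate 3 was 1.05 (95% interval 1.01 to 1.08). The test that called these genes favours genes with similar values in the 3 B220+ libraries, so selection alone draws this ratio toward 1. The ratio shows that most genes called higher did not follow the markers between these replicates. It does not decide how far plasmacytoid cells raised other genes, and such cells stay open as the source of the markers themselves. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, and the highest of the others gave 0, including the other 3 splits that part all 3 replicate pairs, but 10 splits are too few for a share under 0.05. The biological difference that the design names, B220 on the cell surface, stays open with any difference in sorting that went with it.

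The second pattern is the rise of Csf2 with its neighbour P4ha2. If the B220− cells were B220+-like cells diluted by conventional T cells, Trdc, which conventional T cells lack, would rise as much as Csf2, but Csf2 rose by 2.02 more on the log2 scale (SE 0.31), and 0 of the 26 tested natural intraepithelial genes reached its fold change. Transcription running from P4ha2 into Csf2 would leave reads between them. The 3 annotated models in the 116 kb gap held 1 count in the B220− and 11 in the B220+ libraries. The density over P4ha2 exons predicts 430 in the B220+ libraries, but unspliced read-through RNA may be sparser than spliced P4ha2 RNA. P4ha2 lies on the plus strand and Csf2 on the minus strand, so such reads would be antisense to Csf2. The counts therefore do not decide on read-through. Shared control of the neighbourhood cannot be told apart from 2 separate changes: besides Csf2, its antisense model and P4ha2, 1 of the 8 tested genes within 500 kb of Csf2 was called higher (Slc22a21), against 5.55% elsewhere (one-sided Fisher's exact test, p = 0.367), and 8 genes are too few to decide.

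The third pattern is the Cd4, Cd5 and Cd28 left in the B220+ libraries, at 4.23% (limits 2.93 to 6.11), 4.05% (2.04 to 8.03) and 4.95% (3.75 to 6.52) of their B220− levels. These limits are a fixed multiple of the SE of each log2 fold change (0.27, 0.49 and 0.20). They may be narrower than 95% intervals. Carry-over of B220− cells would leave Il17a at the same share, but Il17a stood at 0.206%, with an upper 95% counting limit of 0.604%, below the lower limit of each of the others. This argues against unselected B220− cells as the whole source of these transcripts. Carry-over limited to B220− cells without Il17a was not tested, and low expression by the B220+ cells themselves may account for the remainder. Other residual levels differed in the same libraries, at 8.41% for Cd6, 9.76% for Icos and 11.2% for Cd8b1.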
